A study of Mus musculus with 6 samples.

How the data were processed

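The counts analysed here are those the authors deposited, 1 file per library, with read pairs per gene not normalized. Per the file headers, pairs were counted with featureCounts 1.6.0 as reverse-stranded, over exons summed by gene, with the GENCODE vM36 annotation. Per the submitters' processing notes, STAR 2.7.9a, FastQC 0.11.8 and the GRCm39 build were used. Per the labels' protocols, RNA came from frozen subcutaneous tumors and libraries were made with poly(A) selection. Coordinates are those of the files. The 6 libraries held 11684055 to 13506295 counts over 78239 features, 0 of the rows named no gene, and no pair of libraries held the same values. Gene symbols were matched by stable identifier for 51498 features (65.82%), which held 91.62% to 99.44% of the counts of a library. The counter's handling of reads shared by paralogs makes values of H2, globin and histone genes uncertain.

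Triple-treated and vehicle libraries, 3 of each, were compared with edgeR 4.0.16 (R 4.3.3): TMM normalization, its filter on low counts by group, robust quasi-likelihood fits with the group as the sole term, and Benjamini-Hochberg adjustment over 15662 genes at a threshold of 0.05. CPM values use TMM-scaled library sizes. The ± of a fold change is its standard error, and the ± of CPM or percent is the SD. Of 36 gene lists fixed before the data were examined, the 34 with 3 or more tested genes went to camera (limma 3.58.1) with a preset inter-gene correlation of 0.01. The alternatives to it were an estimated correlation and fry. Fry asks another question, whether the genes of a list move one way, and does not compare them with other genes. With an estimated correlation camera also takes its degrees of freedom from the 6 libraries and not from the genes. A call lost in that setting need not reflect correlation. A list's score is the mean log2 CPM (prior count 2) of its tested genes, centered over the libraries. The log2 ratio of Cd8a to Foxp3 used a prior count of 0.5, and single values were compared by exact permutation, two-sided, which cannot give a p below 0.1 for 3 against 3. Principal components used the 500 most variable genes. A floor is 3 counts, and floors and Wilson intervals (95%) cover counting error only.

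The rule for named genes was fixed before the data were examined. It takes, in each direction, 10 genes past the threshold with non-overlapping groups, a mean CPM of 1 or more and a symbol that is not a predicted gene, ranked by fold change. Where fewer than 5 pass it takes the 10 with the smallest p, which was read as the smallest p among the genes meeting the other conditions. It adds up to 4 members of each list with the smallest p and a fixed set (Rb1, Trp53, Pdcd1, Ctla4, Cd274, Cd8a, Foxp3, Gzmb, Ifng, Cxcl9, B2m, H2-K1, Ascl1, Neurod1, Pou2f3, Yap1, Mki67, Src, Kit, Xist). From each list the 2 members with the smallest p were followed through the alternatives and serve as examples. This number was set after values had been seen. It replaced a selection of examples made by hand, from which genes that turned direction under an alternative had been left out.

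Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile scaling, no filter on low counts, a filter of CPM of 1 in 3 samples, DESeq2 1.42.0, limma-voom with and without sample weights, non-robust fits, other thresholds, counts without mitochondrial genes, the replicate number as a block and leaving out each library. Another 4 were chosen after seeing the data: leaving out the ribosomal-like features, leaving out 2 pairs of libraries, and a covariate for Y-linked transcripts. These 4 were run for the numbers of genes and lists called only.

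The fit was tested on simulated data for the same 15662 genes and 6 libraries. The changed genes were drawn from those with a mean CPM of 1 or more, and each gene was simulated independently. Variation that genes share within a library, such as that of stroma or muscle, was not simulated. The numbers found therefore need not hold for the real comparison. With dispersions as estimated per gene, it found 45 of 100 genes changed 2-fold and 72 of 100 changed 4-fold, with 11 false calls. At a dispersion of 0.01 for every gene, it found 96 and 98 of 100, with 14 false calls. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.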

Results

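Poly(A) RNA was sequenced from subcutaneous tumors grown from RP cells, a murine small cell lung cancer (SCLC) line lacking Rb1 and Tp53, in F1 hybrid mice that the labels describe as female and 8 weeks old. Treatment began at a tumor volume of about 50 mm3. In 3 libraries the tumors had received dasatinib, an inhibitor of SRC family, ABL, KIT and PDGF receptor kinases, at 30 mg/kg daily together with antibodies against the checkpoint receptors PD-1 and CTLA4 at 100 µg per mouse each. These are called triple-treated here, and 3 vehicle libraries served as controls. Gene counts summed to 12142073, 13506295 and 13365484 in the vehicle libraries and to 13323065, 11838240 and 11684055 in the triple-treated libraries. The labels do not state outright that each library came from its own mouse, so the p-values measure the spread between these libraries. Dasatinib and the antibodies were given together, and their separate effects were not analysed here.

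The genes deleted in the parental cells were examined first. Rb1 (chromosome 14, 73421113 to 73563262, GRCm39) gave 1630 to 2909 counts per library, with 169 ± 38.4 CPM (counts scaled to the TMM-adjusted library size; SD, n = 3) in vehicle and 183 ± 14.3 in triple-treated tumors. Trp53 (chromosome 11, 69471185 to 69482699) gave 204 to 343 counts, with 23.8 ± 5.57 CPM in vehicle and 20.4 ± 3.25 in triple-treated tumors. Which exons were removed is not given in the sources used here, and counts summed over a whole gene, host cells included, cannot check a deletion of part of it.

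The comparison of triple-treated with vehicle tumors asks how the combination altered the transcriptome of the tumor and its microenvironment, a subject named in the title of the study. Transcripts of macrophages, matrix fibroblasts, complement and chemokines averaged lower in triple-treated tumors as sets, and those of chaperones, mitochondrial genes and skeletal muscle averaged higher. Of 15 sets called, 12 lost the call or turned direction when 1 of the 6 libraries was left out. With an estimated inter-gene correlation, a setting that also has fewer degrees of freedom, 0 of 34 sets tested were called. None of 15662 genes passed an adjusted p of 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (0 higher, 0 lower, smallest adjusted p 0.999). At an unadjusted p under 0.05 there were 202 genes, where uniform p-values would give 783. The other splits of the 6 libraries into 3 and 3 gave 224 to 2058, so the split by treatment gave the fewest. The median standard error of a log2 fold change was 0.22, so a typical 95% confidence interval reached 0.50 to either side. The groups did not overlap for 489 genes that were higher and 444 that were lower in all triple-treated tumors, together 5.96% of genes, against the 10% that chance gives for 3 against 3. With limma-voom 0 genes were called, with or without sample weights, and with DESeq2 2 were called, both lower, Lars2 and a feature without a symbol. When genes with low counts were kept, edgeR called 37 genes, 30 of them higher and led by the muscle genes Klhl41, Ckmt2 and Pdlim3, and 7 lower. Leaving out the first triple-treated library gave 11 higher genes, 9 of them on the skeletal muscle list and the other 2 the muscle genes Tnnc2 and Ttn. Of the 9, Acta1 alone was among the genes tested in the main fit, since the filter follows the size of the smaller group. The library left out held 92 muscle counts, against 2994 and 10966 in the other triple-treated libraries. Leaving out the first vehicle library gave 4 lower genes, Lars2, Mir6236 and 2 features without a symbol. These 4 and the 2 called with DESeq2 belong to the set of ribosomal-like features described below. The genes named for these alternative counts were chosen after their values were seen.

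Because fewer than 5 genes passed in either direction, the genes with the smallest p among those whose groups did not overlap are given as values, not as changes. On the higher side, Dner, a Notch-binding receptor of neurons (chromosome 1, 84347560 to 84673942), had 132 ± 9.30 CPM in vehicle and 175 ± 4.61 in triple-treated tumors, a log2 fold change of 0.41 ± 0.11 (SE). Robo1, an axon guidance receptor, stood at 0.49 ± 0.16, and Tox3, a nuclear HMG-box protein, at 0.45 ± 0.15. The osmolyte transporter Slc5a3 stood at 0.64 ± 0.20, the actin regulator Cap2 at 0.67 ± 0.22 and the nucleosome-binding protein Hmgn5 at 0.41 ± 0.12. The sarcomere genes Pdlim3 and Mylpf had log2 fold changes of 3.52 ± 0.97 and 2.84 ± 0.83, in tumors that differed in muscle transcripts, and mt-Nd5 and mt-Nd4 belong to the mitochondrial set. On the lower side, the fractalkine receptor Cx3cr1, a monocyte and macrophage gene (chromosome 9, 119877749 to 119898945), had 2.12 ± 0.369 CPM in vehicle and 0.388 ± 0.296 in triple-treated tumors, a log2 fold change of −2.43 ± 0.62. The long noncoding RNAs Malat1, Kcnq1ot1 and Zfhx2os stood at −1.39 ± 0.39, −0.73 ± 0.23 and −0.68 ± 0.21. Arhgap33, Gpr162 and Spaca6 stood at −0.44 ± 0.15, −0.59 ± 0.19 and −0.68 ± 0.21, and the linker histone Hist1h1d at −2.99 ± 0.91. Lars2, at −4.73 ± 0.98, and Mir6236, at −6.16 ± 1.61, belong to a set of ribosomal-like features whose share of counts was highest in the first vehicle library. Without that library the log2 fold changes were −3.02 for Lars2, −2.89 for Mir6236, −1.40 for Hist1h1d and −0.78 for Malat1. Over the fits without 1 library they ran from 1.94 to 4.12 for Pdlim3, 1.54 to 3.32 for Mylpf and −3.06 to −1.94 for Cx3cr1. Malat1, Hist1h1d, Pdlim3 and mt-Nd5 passed the threshold when genes with low counts were kept, and Lars2 did so with DESeq2, at an adjusted p of 0.0474.

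Macrophage transcripts were lower as a set in triple-treated tumors. Of the 20 genes on the macrophage and monocyte list, 19 had negative log2 fold changes, with a median of −0.88, or 1.85-fold higher in vehicle. Besides Cx3cr1, the scavenger receptor Msr1 had 6.34 ± 5.34 CPM in vehicle and 2.10 ± 2.12 in triple-treated tumors (SD, n = 3). The alternatively activated macrophage list was lower in 8 of 9 genes with a median of −1.24. On it, the mannose receptor Mrc1 had 22.2 ± 28.7 CPM in vehicle against 4.17 ± 4.21, and the folate receptor Folr2 had 2.88 ± 3.80 against 0.668 ± 0.808. The complement list was lower in 15 of 16 genes (median −0.91; properdin gene Cfp −0.82 ± 0.35, anaphylatoxin receptor C5ar1 −1.89 ± 1.06), and the chemokine list in 12 of 14 (median −0.65; monocyte attractants Ccl7 −2.18 ± 1.002 and Ccl2 −1.46 ± 0.95). The MHC class II list was lower in 8 of 8 genes, with a median of −0.69, its transactivator Ciita at −0.67 ± 0.32 and H2-DMa at −0.71 ± 0.61. The fibroblast and matrix list was lower in 21 of 21 genes with a median of −0.54, among them Pdgfra at −0.85 ± 0.48 and Thy1 at −0.81 ± 0.71. Over the fits without 1 library the log2 fold changes ran from −2.83 to −0.63 for Msr1, −3.63 to −0.45 for Mrc1, −3.78 to −0.05 for Folr2, −2.96 to −0.61 for C5ar1, −3.30 to −1.59 for Ccl7 and −3.20 to −1.02 for Ccl2. They ran from −1.38 to −0.15 for H2-DMa, −1.20 to −0.22 for Pdgfra and −1.67 to −0.36 for Thy1. The values nearest 0 were those without the third vehicle library, or for Thy1 without the first triple-treated one, and the lowest were those without the third triple-treated library.

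These sets were called by camera with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjusted p of 2.29e-09 for macrophages, 0.00372 for alternatively activated macrophages, 7.25e-05 for complement, 0.00198 for chemokines, 0.00262 for MHC class II and 7.17e-04 for fibroblasts. With an estimated correlation all 6 calls were lost, each at an adjusted p of 0.743. No member passed the gene test, adjusted over all genes (0) or adjusted over the list alone (0). The tumors of both groups spanned a wide range. The macrophage score, the mean centered log2 CPM of the list, was 0.44, −0.47 and 1.66 in the vehicle libraries and −2.01, −0.55 and 0.93 in the triple-treated ones. Compared by library, its group difference was −1.09 (exact permutation p 0.4), and that of the fibroblast score −0.77 (exact permutation p 0.6). Without the third vehicle library the adjusted p became 0.0732 for macrophages, 0.945 for alternatively activated macrophages, 0.751 for complement, 0.756 for chemokines and 0.707 for MHC class II. Without the first triple-treated library these were 0.0145, 0.264, 0.274, 0.166 and 0.729. The fibroblast list turned direction without either of them, at 0.756 and 0.773.

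**Figure D1:**
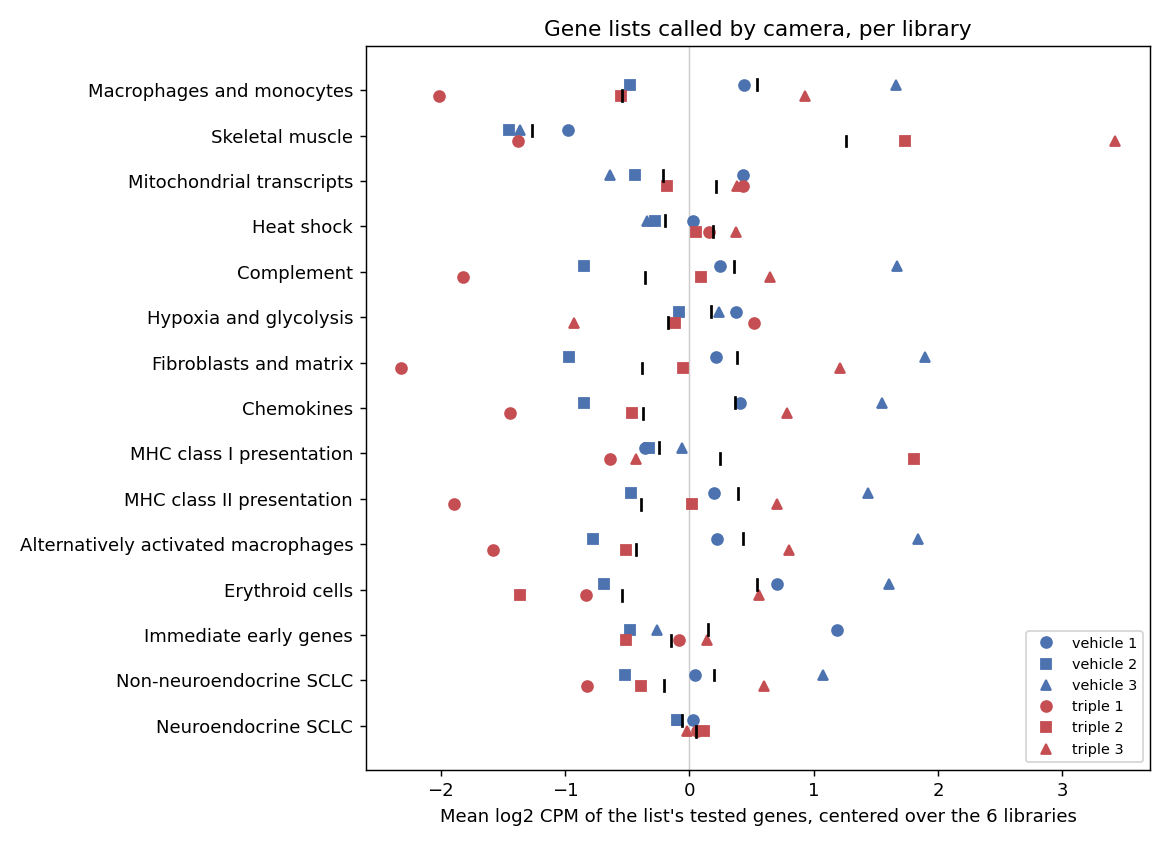
Scores of the 15 gene lists called by camera with the preset correlation. Each point is 1 library (blue, vehicle; red, triple-treated), the x axis is the mean log2 CPM of the list's tested genes centered over the 6 libraries, and black ticks are group means (n = 3). The groups overlap in each list but heat shock, and the macrophage score runs from −2.01 to 1.66.

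Most genes on the lymphocyte lists had few counts in both groups. Cd8a, the CD8 coreceptor, gave 0 to 4 counts per library and Foxp3, the regulatory T cell factor, gave 0 to 5, where a count of 0 allows up to 3 counts, or 0.217 to 0.263 CPM, by counting error only. Gzmb, which encodes granzyme B, was counted in 1 library of each group, with 9 and 2 counts, and Ifng in a single vehicle library, with 1 count. Pdcd1 and Ctla4, which encode the antibody targets, gave at most 3 and 2 counts. Of 18 cytotoxic lymphocyte genes, 17 had fewer than 10 counts in each of the 6 libraries, leaving Ccl5 at 0.0024 ± 0.67. The same held for 12 of 20 T cell genes, 7 of 12 regulatory T cell genes, 9 of 16 B and plasma cell genes and 11 of 16 neutrophil genes, the neutrophil receptor Csf3r standing at −1.17 ± 1.01, or −0.02 without the third vehicle library. The log2 ratio of Cd8a to Foxp3 was 0.02 ± 3.001 in vehicle and 0.53 ± 0.92 in triple-treated tumors (SD, n = 3; exact permutation p = 0.8, two-sided, the smallest possible being 0.1), and at these counts a difference was not detectable. Without the second vehicle library the difference in this ratio was −0.91.

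Of the immune cell lists with enough genes to test, T cells (5 of 5 lower, camera adjusted p = 0.0718), dendritic cells (0.243), checkpoints (0.738), regulatory T cells (0.817), mast cells (0.817) and B and plasma cells (0.888) were not called. Tested members were those with enough counts, not always the defining ones. Skap1 (26.5 CPM in vehicle) and Bcl11b (13.2) were tested for T cells, while Cd3e (0.122) and Trac (0.415) were not. Fscn1 (149), Kit (40.6), Tox (94.3) and Ikzf4 (9.07) stood on the dendritic, mast cell, checkpoint and regulatory T cell lists. Whether tumor cells carry such transcripts was not tested, so these results cannot be read as the content of those cells alone. Cd4, the helper T cell coreceptor that macrophages also carry, had 1.62 ± 0.676 CPM in vehicle and 0.471 ± 0.347 in triple-treated tumors, a log2 fold change of −1.77 ± 0.63, while Skap1 was at −0.11 ± 0.17. The costimulatory ligand Cd86 was at −1.44 ± 0.92 and the checkpoint receptor Lag3 at −0.59 ± 0.31. Cd274, which encodes PD-L1, had 1.98 ± 1.45 CPM in vehicle and a log2 fold change of −0.31 ± 0.66. Tnfrsf4 was at −0.67 ± 0.51, the mast cell tryptase gene Tpsab1 at −1.62 ± 1.18 and the B cell factor Pax5 at 0.88 ± 0.90. Over the fits without 1 library these ran from −2.48 to −1.36 for Cd4, −2.44 to −0.85 for Cd86, −0.73 to 0.42 for Cd274, −2.34 to 0.61 for Tpsab1 and −0.14 to 2.12 for Pax5. The T cell list was called lower without the second triple-treated library (adjusted p 0.0236), and without the second vehicle library the dendritic (0.0390) and mast cell lists (0.00115) were.

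Interferon response genes leaned higher without passing the test. Positive log2 fold changes were found for 17 of 22 type I interferon genes (median 0.12, camera adjusted p = 0.236) and for 13 of 16 interferon gamma genes (median 0.20, adjusted p = 0.385). Oas3 and Ifit2, of the antiviral response, stood at 0.92 ± 0.48 and 1.03 ± 0.59, Wars at 0.18 ± 0.15, Irf1 at −0.22 ± 0.20 and the chemokine gene Cxcl9 at −0.01 ± 1.22. Over the fits without 1 library these ran from 0.39 to 1.84 for Ifit2 and −0.66 to 1.20 for Cxcl9. Without the first triple-treated library both lists were called higher, at adjusted p of 9.48e-08 and 3.42e-06, as was the type I list without the first vehicle library, at 0.0165. Neither list was called without the second (0.584 and 0.217) or the third (0.102 and 0.891) triple-treated library. Type I scores were 0.41, −0.58 and 0.04 in vehicle and −1.06, 0.28 and 0.91 in triple-treated libraries. Interferon gamma scores were 0.08, −0.49 and 0.31 in vehicle and −1.11, 0.71 and 0.50 in triple-treated ones. Without the third triple-treated library the mean triple-treated score was below that of vehicle for both lists. The MHC class I presentation list was higher as a set (13 of 17 genes, median 1.17, camera adjusted p = 0.00262; adjusted p = 0.743 with an estimated correlation), and its highest score was that of the second triple-treated tumor. The score there was 1.80, against −0.64 and −0.43 in the other triple-treated and −0.36, −0.32 and −0.06 in the vehicle tumors. B2m, the invariant light chain, had 783 CPM in that library and at most 149 in the others, and the immunoproteasome gene Psmb8 had 79.8 against at most 6.45. The group log2 fold changes were 1.53 ± 0.89 for B2m, 1.17 ± 0.82 for H2-K1, 2.55 ± 1.25 for Psmb8 and 3.02 ± 1.51 for H2-Q7, the H2 genes being near-identical paralogs whose counts are uncertain. Without that library the values were −0.24 for B2m, −0.46 for H2-K1, −0.29 for Psmb8 and −0.75 for H2-Q7, and the list was called in the opposite direction, at an adjusted p of 4.86e-04, and without the second or the third vehicle library it was not called, at 0.116 and 0.0732.

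Neuroendocrine transcripts were abundant in both groups. Ascl1, the lineage factor of the main neuroendocrine SCLC subtype, had 1098 ± 114 CPM in vehicle and 1321 ± 213 in triple-treated tumors, a log2 fold change of 0.27 ± 0.16. Neurod1 had 7.92 ± 1.6 and 8.16 ± 2.60 CPM, Yap1 4.58 ± 2.00 and 4.56 ± 1.23, and Pou2f3, the tuft cell factor, was near the floor at 0.437 ± 0.143 and 0.356 ± 0.135. The subtype factor list was not called (adjusted p = 0.398). The neuroendocrine list was higher by a small amount (14 of 21 genes, median 0.11, camera adjusted p = 0.0105; adjusted p = 0.743 with an estimated correlation), with Scg3 at 0.28 ± 0.13 and Insm1 at 0.48 ± 0.23. The non-neuroendocrine list was lower (15 of 17, median −0.36, adjusted p = 0.00665; adjusted p = 0.743 with an estimated correlation), with Lgals3 at −1.07 ± 0.61 (−1.74 to −0.49 without 1 library) and Anxa2 at −0.35 ± 0.23. Its score was highest in the third vehicle and lowest in the first triple-treated library (1.07 and −0.82), as were the macrophage (1.66 and −2.01) and the fibroblast score (1.90 and −2.32). The neuroendocrine call was lost without the second vehicle (adjusted p 0.123), the third vehicle (0.223), the first triple-treated (0.0928) or the second triple-treated library (0.116). The non-neuroendocrine list turned direction without the third vehicle library (0.702) and was not called without the first (0.341) or the second (0.116) triple-treated one.

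Proliferation genes were centered near 0, 13 of 25 being higher and 12 lower, with a median of 0.01, a mean of −0.0024 and an adjusted p of 0.888. Mki67 had 945 ± 200 CPM in vehicle and 926 ± 107 in triple-treated tumors, a log2 fold change of −0.03 ± 0.18 with a 95% interval from −0.45 to 0.39. The mitotic kinase gene Aurkb was at −0.25 ± 0.12 and the replication helicase gene Mcm6 at 0.37 ± 0.19. Genes of dasatinib's kinase targets were not called as a list (12 of 20 lower, adjusted p = 0.307), although they were called lower without the second vehicle (0.0426) or the third triple-treated library (0.0274). Src was at 0.11 ± 0.14 and Kit, which encodes the stem cell factor receptor, at 0.28 ± 0.20. YAP and SRF targets (adjusted p = 0.888, Amotl2 0.34 ± 0.23, Serpine1 −0.72 ± 0.50) were not called. Nor were p53 targets (0.835, median 0.02 but mean −0.02), of which the cell cycle inhibitor Cdkn1a was at −0.43 ± 0.17 and Plk2 at −0.51 ± 0.38. Plk2 was at −0.79 without the second vehicle library and at −0.0071 without the third.

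Chaperone genes were higher as a set in triple-treated tumors. Of 10 heat shock genes, 9 had positive log2 fold changes, with a median of 0.43, or 1.35-fold. The mitochondrial chaperonin gene Hspd1 had 446 ± 44.4 CPM in vehicle and 605 ± 89.8 in triple-treated tumors, and Hsph1 had 177 ± 15.6 and 241 ± 44.3. The list was called by camera at an adjusted p of 6.67e-06 and in each of the 6 fits that left out 1 library, but not with an estimated correlation (adjusted p = 0.228). The correlation estimated for its genes was −0.066, below the preset 0.01, against 0.882 for macrophages and 0.943 for fibroblasts. A correlation above the preset therefore does not account for the loss of this call. Its unadjusted p was 7.84e-07 with the preset and 0.00670 with the estimate, which also takes its degrees of freedom from the 6 libraries. Mitochondrially encoded transcripts were higher in 9 of 11 genes (median 0.41, adjusted p = 2.70e-07; adjusted p = 0.743 with an estimated correlation), and 2 of them passed when adjusted over the list alone. The complex I genes mt-Nd5 and mt-Nd4 stood at 0.89 ± 0.25 and 0.68 ± 0.20. Mitochondrial genes took 2.37 ± 0.545% of counts in vehicle and 3.32 ± 0.667% in triple-treated tumors (SD, n = 3; exact permutation p = 0.2, two-sided, smallest possible 0.1).

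Hypoxia and glycolysis genes were lower in 18 of 19 (median −0.28, camera adjusted p = 2.68e-04; adjusted p = 0.743 with an estimated correlation), with Pfkfb4 at −0.36 ± 0.21 and P4ha1 at −0.32 ± 0.26. That list turned direction without the third triple-treated library (adjusted p 0.338), which held its lowest score, −0.93. Immediate early genes were lower in 13 of 14 (median −0.48, adjusted p = 0.00665; adjusted p = 0.743 with an estimated correlation), with Junb at −0.53 ± 0.30 and Ier3 at −0.77 ± 0.47. Their score was 1.18 in the first vehicle library and at most 0.14 in the others. Without that library the list was called higher instead, at an adjusted p of 0.0155, and without the second triple-treated library it was not called, at 0.139.

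Transcripts of tissues next to or within the graft differed between tumors. Summed over the 15 skeletal muscle genes, counts were 98, 101 and 104 in the vehicle libraries, 92 in the first triple-treated one and 2994 and 10966 in the second and the third. Mylpf, a muscle myosin light chain gene, had 2.95 ± 0.643 CPM in vehicle and 21.1 ± 22.2 in triple-treated tumors, and Casq1, the calcium store protein gene of muscle, had 1.45 ± 0.424 and 7.90 ± 7.32. The log2 fold change of Casq1 was 2.45, and 1.45 without the third triple-treated library. The filter asks for counts in as many libraries as a group holds. It left out muscle genes counted mainly in the second and the third triple-treated libraries, such as Myh4 (388 and 1590 counts). The 3 muscle genes that passed it were called as a set (camera adjusted p = 2.70e-07, and 0.506 with an estimated correlation). Of these, 3 of 3 passed when adjusted over the list alone. Erythroid genes were lower in 5 of 6 (median −1.64, adjusted p = 0.00600; adjusted p = 0.743 with an estimated correlation), with the globin genes Hbb-bs and Hba-a2 at −2.11 ± 1.05 and −1.91 ± 1.04, paralogs that share reads. Over the fits without 1 library these ran from −3.06 to −0.71 and from −3.82 to −1.33. That call was lost without the first vehicle (adjusted p 0.0516), the third vehicle (0.353) or the first triple-treated library (0.0584).

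Vessel and skin lists did not pass the test. Endothelium (13 of 17 lower, camera adjusted p = 0.734) included the angiopoietin receptor Tek at 0.77 ± 0.59 (0.40 to 1.47 without 1 library) and Plvap at −0.36 ± 0.35. Pericytes and smooth muscle (8 of 11 lower, 0.224) included the channel gene Kcnj8 at −0.88 ± 0.36 and Des, also a skeletal muscle gene, at 1.77 ± 0.58, or 0.80 without the third triple-treated library. Endothelium was called higher without the third vehicle library (0.0157) and lower without the third triple-treated one (0.0274). Pericytes were called lower without the first (0.0467) or second vehicle (0.0162) or the second (0.0208) or the third triple-treated library (1.79e-04). Adipocytes (0.618, Cfd 1.91 ± 1.57, and 0.29 to 4.40 without 1 library) were called higher without the third vehicle (0.0157) or the first triple-treated library (4.84e-04). Keratinocytes (0.734, Krt10 0.23 ± 0.39) and Schwann cells (0.879, Pmp22 −0.21 ± 0.30) were not called. Y-linked genes (0.190, Eif2s3y −1.04 ± 1.74, and −7.92 to −0.17 without 1 library) were counted in only 3 of the 6 libraries, and were called lower without the second vehicle (0.00724) or the third triple-treated library (8.42e-05).

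A set of 8 ribosomal-like features, chosen after their values were seen, took 8.82% of counts in the first vehicle library (95% Wilson interval 8.80 to 8.83, counting error only). It took 0.719% and 0.611% in the other vehicle libraries and 0.136%, 0.136% and 0.108% in the triple-treated ones. The group means were 3.38 ± 4.71% and 0.127 ± 0.0165% (SD, n = 3), with no test given, since the features were chosen on these values. The leading feature, ENSMUSG00000119584, has no symbol in the tables used and lies on chromosome 17 from 40157244 to 40159092. The members with a symbol are Lars2, Mir6236 and Gm15564. Ribosomal-like is a label here, and a ribosomal origin of the set was not tested. Without these features 0 genes and 15 lists were called.

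**Figure D2:**
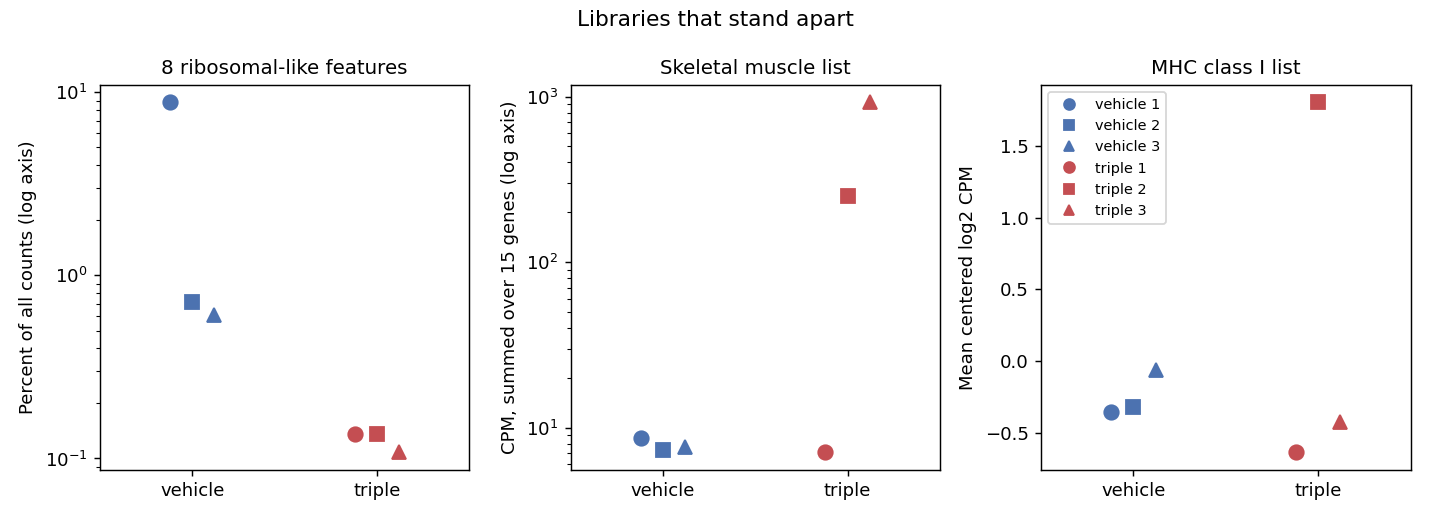
Libraries that stand apart from their group. Each point is 1 library; the panels plot the percent of counts in 8 ribosomal-like features (log axis), the CPM summed over 15 skeletal muscle genes (log axis) and the MHC class I score. The first vehicle library lies at 8.82%, the third triple-treated library at 923 muscle CPM and the second triple-treated library at an MHC class I score of 1.80.

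The main axis of variation did not follow treatment. Over the 500 most variable genes, the first principal component held 69.0% of the variance and placed the first triple-treated and second vehicle libraries (42.7 and 18.7) opposite the third vehicle and the third triple-treated ones (−37.7 and −22.2). The groups accounted for 16.2% of the variance, within the 7.43% to 51.5% that the other splits of the libraries into 3 and 3 gave. Without the first triple-treated library the share was 37.7%.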

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

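Leaving out the ribosomal-like features, leaving out 2 libraries together and the Y-linked covariate were chosen after seeing the data. Both other thresholds could only give 0 genes, since the smallest adjusted p was 0.999. The count of 0 genes held under DESeq2 size factors, upper-quartile scaling, a filter of CPM of 1 in 3 samples, both limma-voom fits and non-robust fits. It also held for counts without mitochondrial genes, without the ribosomal-like features and with the Y-linked covariate. It became 37 (30 higher, 7 lower) when genes with low counts were kept, 2 (2 lower) with DESeq2, 4 (4 lower) without the first vehicle and the third triple-treated libraries, and 3 (3 lower) without the first vehicle and first triple-treated ones. Leaving out 1 library gave 0 to 11 genes, 0 to 11 higher and 0 to 4 lower. The number of lists called went from 15 to 0 with an estimated correlation, to 12 with the Y-linked covariate (8 higher and 4 lower against 5 and 10, with 9 of the 15 kept), and ranged from 7 (without the third vehicle library) to 18 when 1 library was left out. Without the first triple-treated library it was 10 (7 higher, 3 lower). It was 17 (6 higher, 11 lower) without the first vehicle and the third triple-treated libraries. Without the first vehicle and the first triple-treated ones it was 10 (8 higher, 2 lower, 7 of the 15 kept). Of the 15 called lists, 3 (skeletal muscle, mitochondrial, heat shock) kept their call in all 6 fits without 1 library, 12 lost it or turned at least once and 5 of these turned direction. The cause was not tested, beyond the fewer libraries in each fit. By fry, which asks whether the genes of a list move one way and does not compare them with other genes as camera does, 0 lists were called.

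Replicate numbers do not pair the libraries by any label, and the deviations of same-numbered libraries correlated at 0.0394, 0.128 and 0.509, so the pairing was not used. With the replicate number as a block 0 genes and 16 lists were called and 386 genes had an unadjusted p under 0.05, Y-linked genes being the added list (adjusted p 0.00665), while B and plasma cells (0.700), proliferation (0.859) and Yap1 (log2 fold change 0.042) turned direction. Not every library correlated best with its own number, the first triple-treated one doing so with the second vehicle library (0.498).

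Over the fits without 1 library, the camera adjusted p of lists that turned direction at least once or, uncalled, were called in some ranged as follows. It ran from 0.0236 to 0.432 for T cells, 0.575 to 0.945 for regulatory T cells, 0.0546 to 0.769 for checkpoints, 3.42e-06 to 0.894 for interferon gamma, 9.48e-08 to 0.941 for type I interferon, 4.32e-10 to 0.116 for MHC class I, 0.0390 to 0.932 for dendritic cells, 0.261 to 0.910 for B and plasma cells and 0.00115 to 0.832 for mast cells. It ran from 0.0157 to 0.341 for endothelium, 1.79e-04 to 0.756 for pericytes, 2.39e-10 to 0.773 for fibroblasts, 1.41e-06 to 0.702 for the non-neuroendocrine list, 0.134 to 0.899 for proliferation, 0.0274 to 0.932 for dasatinib targets, 0.0696 to 0.888 for YAP and SRF targets and 0.433 to 0.965 for p53 targets. It ran from 3.73e-21 to 0.338 for hypoxia, 9.90e-05 to 0.139 for immediate early genes, 4.84e-04 to 0.818 for adipocytes, 0.427 to 0.910 for keratinocytes, 0.573 to 0.992 for Schwann cells, and 8.42e-05 to 0.769 for Y-linked genes. Of called lists that kept their direction, macrophages ran from 1.75e-22 to 0.0732, alternatively activated macrophages from 6.72e-06 to 0.945, complement from 1.12e-08 to 0.751, chemokines from 5.59e-09 to 0.756, MHC class II from 2.19e-05 to 0.729, erythroid genes from 5.39e-05 to 0.353 and the neuroendocrine list from 9.75e-04 to 0.223.

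Of the 94 named genes that were followed through the alternatives, 18 turned direction under some setting and 8 passed the threshold under some setting. Acta1, a named muscle gene that was not followed, passed edgeR's test without the first triple-treated library (adjusted p 0.0171). Log2 fold changes without 1 library ran from −0.22 to 0.013 for Skap1, −0.50 to 0.45 for Ccl5, −0.29 to 3.08 for Psmb8, −0.75 to 3.58 for H2-Q7, −0.24 to 1.99 for B2m, −0.46 to 1.604 for H2-K1, −0.14 to 2.12 for Pax5, −2.34 to 0.61 for Tpsab1 and −0.58 to 0.14 for Plvap. They ran from −0.11 to 0.29 for Neurod1, −0.25 to 0.40 for Yap1, −0.52 to 0.032 for Pmp22, −0.041 to 0.54 for Plp1, −0.73 to 0.42 for Cd274, −0.66 to 1.20 for Cxcl9, −0.18 to 0.12 for Mki67 and −0.17 to 1.86 for Xist. Other models moved some values by over 1.5-fold. With plain limma-voom B2m was at 0.80, H2-K1 at 0.50, Psmb8 at 1.13, H2-Q7 at 0.96, Pdlim3 at 2.88, Mylpf at 2.17, Casq1 at 1.85, Cd86 at −2.37, Cxcl9 at −1.40, Eif2s3y at −2.03, Tpsab1 at −0.44, Hba-a2 at −2.55, Hist1h1d at −2.20, Lars2 at −4.02 and Mir6236 at −4.46. With sample weights Ccl5 was at 1.12, Ccl7 at −0.996, Cfd at 3.34, Folr2 at −1.48, Mrc1 at −1.71, Hbb-bs at −1.19, B2m at 0.90, H2-K1 at 0.48, Psmb8 at 1.20, H2-Q7 at 1.06, Pdlim3 at 2.78, Mylpf at 2.04, Casq1 at 1.80, Cd86 at −2.38, Cxcl9 at −1.30, Hist1h1d at −1.74, Lars2 at −3.56 and Mir6236 at −3.70. With the replicate number as a block B2m was at 0.71, H2-K1 at 0.47, Psmb8 at 1.19, H2-Q7 at 1.20, Pdlim3 at 2.93, Lars2 at −3.97, Mir6236 at −4.36, Tpsab1 at −0.85 and Eif2s3y at −1.90. With weighted limma-voom the values were 0.15 for Csf3r, 0.48 for Tpsab1, 0.19 for Yap1 and 0.24 for Cd274, and Yap1 was at 0.041 with plain limma-voom. Ccl5 was at −0.0018 with DESeq2 size factors and −0.014 with upper-quartile scaling, where Cxcl9 was at 0.0033. Keeping genes with low counts put Yap1 at 0.011 and Cxcl9 at 0.0090, and DESeq2 put Cxcl9 at 0.0071. The difference in the log2 ratio of Cd8a to Foxp3 ran from −0.91 to 2.08 and the variance between groups from 14.6% to 37.7% without 1 library.

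Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. With 0 genes called in the real split and 0 at most in the others, the splits say nothing on genes. For lists, 5 of the 10 gave at least the real 15, and the highest other gave 25. The split setting the first vehicle, the third vehicle and the third triple-treated libraries against the rest gave 2058 genes at an unadjusted p under 0.05 (real split 202). These 3 are also the libraries with Y-linked counts and those with positive macrophage scores (0.44, 1.66 and 0.93), which this split cannot tell apart.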

Other observations

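Apart from the test of mitochondrial tRNA synthetases beside Lars2, the tests in this part were chosen after the results they bear on had been seen. Of these, the tests of macrophages against other stroma and of Xist replaced earlier versions after those had given their results, and the histone test, which in its first form over the whole groups had met its bound, was divided by library. Mycl, a MYC family gene often amplified in SCLC (chromosome 4, 122889445 to 122896278), averaged 8988 CPM and ranked 3 of 15662 genes, with a log2 fold change of 0.17 ± 0.15 between the groups. Its relatives Mycn and Myc ranked 9170 and 12221, and Nfib, a transcription factor gene also gained in SCLC, ranked 21 with 1987 CPM. A gain of copies could raise a whole neighborhood. The 14 tested genes within 250 kb of Mycl, Cap1 (rank 8) and Ppie (rank 49) among them, had a median of 60.8 CPM, at percentile 95.87 of 10000 windows of as many genes (median 26.5, 95th percentile 58.7). This lies just past the bound that had been set. The windows compare expression levels within these tumors, without a reference for the usual level of these neighbors. The percentile therefore cannot tell a gain of copies from neighbors that are highly expressed without one. A gain is a hypothesis only, since copy number was not analysed here.

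The second triple-treated tumor had high antigen presentation transcripts, while other interferon genes stood closer to the other tumors. Nlrc5, the transactivator of MHC class I genes (chromosome 8, 95160984 to 95253900), had 82.3 CPM there and 1.94 to 8.03 elsewhere, 10.3-fold over the highest other library. Psmb8 was 12.4-fold, Tap1 11.1-fold, B2m 5.27-fold and H2-K1 4.63-fold over the highest other library, while Stat1 was 1.16-fold and Irf1 0.820-fold. The median log2 ratio of this library to the mean of the others was 2.57 over 17 MHC class I genes, 0.53 over 16 interferon gamma genes and −0.06 over 22 type I interferon genes. Nlrc5 was chosen after its values were seen, and no explanation was tested.

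Ribosomal-like features, a set chosen on these values, were highest in the first vehicle library and higher in each vehicle than in each triple-treated library. If poly(A) selection had left more RNA without a poly(A) tail, replication-dependent histone transcripts would be high too. They scored 1.22 above the highest other library in the first vehicle library, and 13 of 14 were highest there (median log2 fold change between groups −0.64, 12 of 14 lower), so incomplete selection remains a candidate explanation for that library. In the second and the third vehicle libraries they scored 0.19 above the triple-treated ones (SD 0.15), too little to tell that explanation from a treatment effect. For Lars2, a lowering of mitochondrial tRNA synthetases by treatment was argued against by the median of −0.018 over the other 16 (range −0.16 to 0.27).

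Macrophage and matrix transcripts averaged lower in triple-treated tumors, and the share of host stroma in each tumor piece may set both: their scores correlated over the 6 libraries (Pearson r 0.973, exact permutation p 0.00278; Spearman rho 0.943, p 0.0167; r 0.864 without the third vehicle and first triple-treated libraries). Of 2 relations computed, this one had Benjamini-Hochberg adjusted p of 0.00556 for r and 0.0333 for rho. The other, of log2 Xist CPM with the mean macrophage and fibroblast score, was set aside because its libraries form clusters. Its Pearson r was −0.832 (exact permutation p 0.0361) and its Spearman rho −0.829 (p 0.0583). A loss of macrophages beyond other stroma was tested first as the macrophage score minus the mean of the fibroblast, endothelial and pericyte scores, which differed by −0.72 (triple-treated minus vehicle) with groups that just did not overlap (0.11 and 0.099 at the nearest; exact permutation p 0.1, the smallest possible), and this met the bound then set. That test was replaced, after its result was seen, by separate gaps because the lists differ in amplitude: −0.32 to fibroblasts (exact permutation p 0.4), −1.06 to endothelium (0.2) and −0.78 to pericytes (0.2), each with overlapping groups. The explanations cannot be told apart, since the answer depends on which version is used and 3 libraries a group cannot go below 0.1.

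Y-linked transcripts were counted in 3 of the 6 libraries, although the labels describe female hosts: 65, 0 and 195 counts in vehicle and 0, 0 and 138 in triple-treated tumors. Where present they stood at 3.56, 2.95 and 3.78 per 1000 fibroblast and macrophage counts, a 1.28-fold range. Hosts of a single sex, with the Y-linked level set by the share of stroma, are argued against. At the lowest of these ratios the second triple-treated library would hold 45.4 Y-linked counts and held 0. This expectation takes Y-linked transcripts to come from host stroma alone. Xist ran from 41.4 to 1315 CPM, 31.8-fold. It stood at 1315, 960 and 1027 CPM in the libraries without Y-linked counts and at 377, 41.4 and 275 in those with them. Xist was lowest in the third vehicle library, which held the most stromal counts, 66016. The first triple-treated library, with 960 CPM, held the fewest, 3243. A host stromal source alone is argued against by the ratio of Xist to stromal counts, which differed 4.79-fold among libraries without Y-linked counts. Hosts of both sexes, tumor cells that differ in Xist and Y-linked transcripts from outside the stroma were not tested and remain open.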
